A study of Oryza sativa with 4 samples.

How the data were processed

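Small RNA was measured in 4 flag leaf libraries, 1 per senescence stage, grouped by the stage in the labels. Per the labels' protocols, RNA of 15-30 nt was excised from a gel, ligated to adapters, amplified and sequenced on an Illumina GA IIx. CASAVA 1.7 is named in the submitters' processing notes. The adapter trimming, the miRNA caller, the aligner and the genome build are not given in the sources used here.

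The miRNA table holds RPM values that, per the file headers, the authors called TPM. No length scaling was applied to them, since every value is a whole multiple of the value of 1 read. Whole reads were recovered from 100% of the values (tolerance 0.1 read), with library totals of 14428266 (US), 20036178 (ES), 20003476 (MS) and 11525493 (LS), or 80.66, 83.9, 87.02 and 91.4% of the reads in the tag files. The deposited position table gives an abundance in counts, which equals the sum of the recovered reads for 350 of 350 sequences. The authors' tag files give raw counts per distinct tag of 16 to 28 nt, with no header. The table's reads exceeded the exact tag counts by 2.753, 0.6032, 0.5006 and 4.422% in the same order. In the position table the hairpin end matched its start and length in 8 of 576 rows, and the folding energy, hit number and p value columns each held 1 value, so these were left out. The start and end of each miRNA were used as deposited by the authors.

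The 576 rows of the table were reduced to 350 distinct sequences, each counted once. The planned scaling was TMM on counts. The deposited values are already normalized and took its place, as the design allowed, and TMM became an alternative. A sequence was called higher or lower when it differed at least 2-fold with at least 10 RPM in the higher library. A library at 0 was set to a floor of 3 reads. Ratios carry exact conditional binomial (Clopper-Pearson) 95% intervals from the recovered reads, and length shares carry exact binomial intervals. These describe the libraries and not the stages. The 5 planned comparisons were each later stage against US, MS against ES and LS against MS; LS against ES was added after the data were seen. Comparisons with US share that library, so agreement between them partly reflects it.

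Sequences were named by a rule fixed before the data were examined. It takes the 10 largest ratios each way against US and the 5 largest each way between successive stages, with at least 50 RPM in the higher library and at least a 2-fold difference. It also takes the 5 most abundant sequences per library and every family of 10 fixed lists. The members miR169r-5p and miR169b, the tag TTGACAGAAGAGAGTGAGCAC and N_osa_492, N_osa_702, N_osa_227 and N_osa_90 fall outside the rule and were chosen after their values were seen. The lists covered SPL and phase change, auxin signalling, NAC, MYB and TCP factors, leaf growth and polarity, copper and redox, nutrient supply, NF-Y, GRAS and F-box regulators, the small RNA machinery, monocot or rice lineage families, and 2 panicle families as markers of another tissue. Families were summed over their named sequences in the table. Families were also counted from 39 known mature sequences of 32 families in the tag files, written from general knowledge after the files were seen. Listed families that the authors' table does not name and whose sequences were not looked up in the tag files (miR157, miR437, miR440, miR1318, miR1423, miR1862 and miR1868) were not analysed here.

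Alternatives were median-of-ratios size factors, TMM, tag-file totals, no filter with a pseudocount of 0.5 reads, a minimum of 100 RPM, a recount from the tag files, the nearer bound of the counting interval, and for families the most abundant member or the tag files. For length shares they were distinct tags, reads of 18 to 26 nt, and tags seen at least 2 times. The calling code was tested on simulated data for LS against US over 350 sequences. It recovered 51 of 51 sequences with a 4-fold change above the minimum and called 0 of 23 unchanged ones, and 96.29% of the intervals covered the true ratio. The simulated counts held counting error only, with no PCR copies or spread between plants. No simulated ratio lay near the 2-fold limit, so this checks the code and not the calls near that limit. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 for TMM and DESeq2 1.42.0 for size factors only.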

Results

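Small RNA was sequenced from field-grown flag leaves of rice (Oryza sativa), cultivar Pusa Basmati 1, the uppermost leaf below the panicle. The design follows senescence of that leaf through 4 stages with 1 library each. The un-senesced library (US) was labelled panicle development, the early (ES) and mid (MS) senescence libraries grain filling, and the late library (LS) seed maturation, so that senescence and plant age advanced together. The libraries held 17886772 (US), 23881096 (ES), 22987122 (MS) and 12609518 (LS) reads of 16 to 28 nt. The authors' miRNA table listed 350 distinct mature sequences, of which 38 carried a miRNA name from 29 families and 312 carried only the authors' own number. No stage had a replicate library, so no test between stages was possible. All intervals are 95% intervals that cover counting error only, and PCR copies are not independent molecules. Levels are RPM, reads scaled to a common library total, as deposited by the authors.

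The 21-nt class, the size of most miRNAs, held a smaller share of reads in US than in the later libraries, and the 24-nt class, the size of siRNAs of the DNA methylation pathway, held a larger share in US. The 21-nt share was 13.06% in US (exact binomial interval 13.043 to 13.074%), 16.55% in ES (16.533 to 16.563%), 18.29% in MS (18.27 to 18.301%) and 17.98% in LS (17.96 to 18.003%). The 24-nt share was 21.33% in US (21.315 to 21.353%), 18.05% in ES (18.034 to 18.065%), 18.16% in MS (18.147 to 18.179%) and 16.2% in LS (16.184 to 16.225%). Adenine was the first base of 63.8% of 24-nt reads in US, 61.7% in ES, 59.1% in MS and 59.9% in LS. Counted once each, distinct tags of 24 nt made up 37.9% of all tags in US and 27.3% in LS. Reads of 16 nt held 14.98% of the US and 14.85% of the ES library but 5.23% of MS and 4.27% of LS, which lowers the share left for every other length in US and ES.

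**Figure D1:**
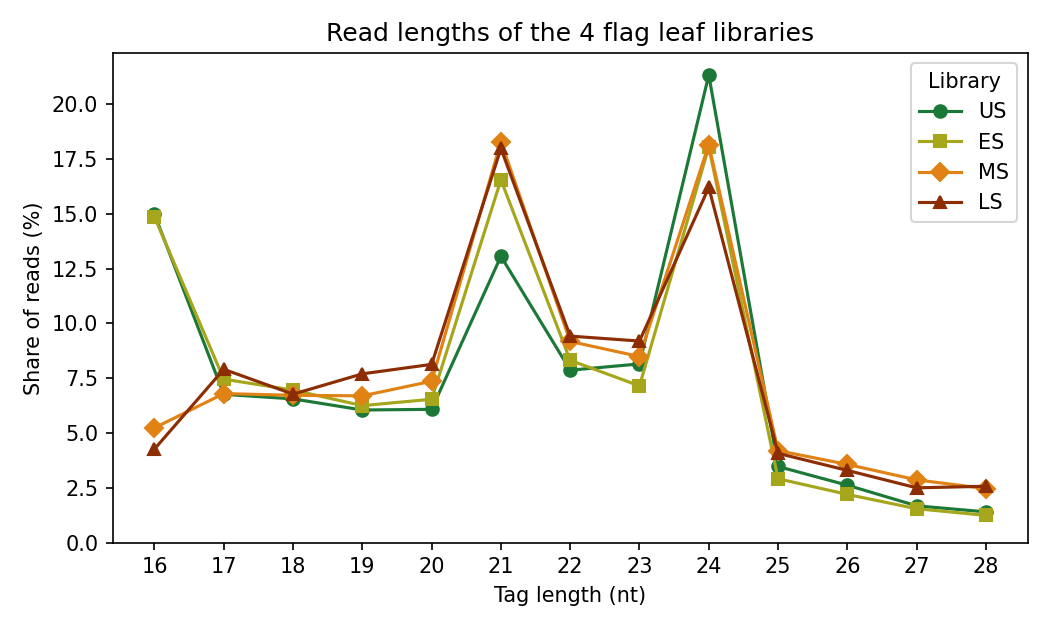
Share of reads (%, vertical axis) by tag length (nt, horizontal axis) in each of the 4 libraries, 1 line per library. The 21-nt share was 13.06% in US and 16.55 to 18.29% in the later libraries, and 16-nt reads held 14.98 and 14.85% in US and ES against 5.23 and 4.27% in MS and LS.

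A few sequences held most of the reads in the authors' table. The 5 most abundant took 82.95% of the table's reads in US, 74.52% in ES, 73.5% in MS and 73.28% in LS. N_osa_114 (TTGAGTGCAGCGTTGATGAACC, chromosome 2, 3280862 to 3280883) led in US with 11690.2 RPM and in ES with 8613.6 RPM, and reached 5075.1 RPM in MS and 5993.1 RPM in LS. It shares 18 nt with miR397a, a laccase regulator, starting 3 nt later, as does N_osa_574, which stood among the top 5 in US (2293.8 RPM) and ES (2202.7 RPM). N_osa_271 shares 20 nt with miR166a-3p, starting 1 nt earlier, and it led in LS with 6840.1 RPM. miR159b, which targets GAMYB-type transcription factors, was the most abundant sequence of the table in MS at 5547.3 RPM. Ranks here are within the table. The known sequence miR444b.2, outside it, had 6297, 7826.4, 9792.3 and 6404.6 RPM of all tag reads in US, ES, MS and LS. On that scale miR159b had 4807.1 RPM in MS. miR167d-5p, a regulator of auxin response factors, was in the top 5 of US (2590.3 RPM), MS (2420.4 RPM) and LS (2635.4 RPM). miR1432-5p entered the top 5 in ES alone, and miR1425-5p in MS (1670.9 RPM) and LS (2473.9 RPM). Chromosome positions are those of the authors' table, whose genome build name is not given in the sources used here, and gene annotation around them was not analysed here.

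Early senescence was set against the un-senesced leaf first. miR1432-5p, a monocot miRNA (chromosome 7, 24061942 to 24061962), was 23.5-fold higher in ES (95% interval 22.42 to 24.65), at 2903.9 against 123.6 RPM. miR159b (chromosome 1, 1214187 to 1214207) was 3.66-fold higher (3.61 to 3.71), at 5761.8 against 1575.7 RPM, and miR168a-5p, which targets the ARGONAUTE gene of the miRNA pathway, was 2.73-fold higher (2.65 to 2.81). miR535-3p stood at 0.211 times its US level (0.188 to 0.237), at 19.5 against 92.1 RPM. miR393a, which targets the TIR1/AFB auxin receptors, stood at 0.315 times its US level (0.302 to 0.329), at 153.6 against 487.1 RPM. Among 56 sequences with at least 10 RPM in the higher library, 16 were at least 2-fold higher in ES and 6 were at least 2-fold lower. Of the 26 with a miRNA name, 5 were higher and 4 lower. Of the 30 with only a number, 11 were higher and 2 lower.

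Of the numbered sequences in this comparison, N_osa_586 (TTTGGCTTGCAACGTTTGACC, chromosome 7, 4144833 to 4144853, and chromosome 12, 19822125 to 19822145) had 0.139 RPM in US and 124 RPM in ES. N_osa_524 (AAAAAGTATATCGAGGTACCG, chromosome 6, 8836391 to 8836411, and chromosome 9, 12938742 to 12938762) had 0.277 RPM in US and 78.9 RPM in ES. Both were nearly absent from US and present in each later library, and their ratios rest on few US reads (894.7-fold, interval 247.4 to 7392.2, and 284.6-fold, interval 110.9 to 1045.9). N_osa_726 was 26.8-fold (19.1 to 38.8) and N_osa_42 21.45-fold (18.3 to 25.3) higher in ES.

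By family, 4 of the 19 listed families above the minimum were higher in ES and 3 were lower. In the list of NAC, MYB and TCP regulators, miR159 (3.43-fold, 3.38 to 3.48) and miR319, a TCP regulator (2.26-fold, 1.79 to 2.88), were higher, while miR164, a NAC regulator, was at 0.854 times its US level. The miR319 ratio was 1.88 under TMM and 1.825 under median-of-ratios scaling, below the limit. In the auxin list, miR393 was lower and miR167 stood at 0.699 times its US level (0.689 to 0.709). In the SPL and phase change list, miR535 and miR156 were lower and miR172, which targets AP2-type factors, was 1.97-fold higher (1.565 to 2.496), just short of the limit, and 2.04-fold from the tag files. The miR156 value covers only miR156f-3p, from the opposite strand, and miR156k. The canonical miR156a-5p sequence, which targets SPL factors, is outside the authors' table and went the other way in the tag reads, with 941 RPM in US and 1638 RPM in ES (1.74-fold, 1.71 to 1.77). It was 18.7% of the US reads that hold its bases 4 to 19, and TTGACAGAAGAGAGTGAGCAC, also outside the table, had 3766.8 RPM in US and 7058.2 RPM in ES. Neither member of the leaf growth list, miR166 (1.55-fold) and miR396 (0.726 times), passed the limit, nor did the NF-Y, GRAS and F-box list, miR169 (0.731 times), miR171 (0.976 times) and miR394 (1.2-fold). The table's miR166 sum covers only miR166g-3p and miR166k-3p, and canonical miR166a-3p in the tag files was at 1.305-fold (1.288 to 1.322). Tags that hold its bases 4 to 19 had 5947.1 RPM in US and 5890.6 RPM in ES. The 2 miR169 sequences of the table differed, miR169r-5p at 47.5 RPM in US and 14.1 in ES and miR169b at 10.9 and 28.6 RPM. From the tag files, as miR169a and miR169b, the family was 2.67-fold higher in ES (2.3 to 3.1). Of the 2 small RNA machinery families in the authors' table, miR168 was above the limit and miR162, a regulator of the Dicer-like gene, was at 1.4-fold. Of the 3 monocot families in the authors' table, miR1432 alone was above the limit, beside miR1425 (1.18-fold) and miR1850 (1.16-fold). From the tag files, miR444 was at 1.243-fold (1.234 to 1.252). miR827, the one nutrient family in the table, was at 1.14-fold (0.977 to 1.34).

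Mid senescence was set against the un-senesced leaf next. miR827 (chromosome 2, 24759029 to 24759049), which targets phosphate transporters of the SPX-MFS type, was 8.52-fold higher in MS (7.5 to 9.72), at 152.4 against 17.9 RPM. miR1432-5p was 7.7-fold higher (7.33 to 8.08), at 950.9 RPM, and miR159f was 4.3-fold higher (4.14 to 4.46), at 946.2 against 220.3 RPM. miR159b was 3.52-fold (3.47 to 3.57) and miR168a-5p 2.7-fold (2.62 to 2.78) higher. miR164a (chromosome 5, 15874055 to 15874075) stood at 0.16 times its US level (0.134 to 0.19), at 8.2 against 51.2 RPM. miR396c-5p, which targets growth-regulating factors, stood at 0.381 times its US level (0.361 to 0.401), miR393a at 0.36 times (0.345 to 0.374) and miR535-3p at 0.303 times (0.274 to 0.335). N_osa_114 was at 0.4341 times its US level (0.4308 to 0.4375). N_osa_586, N_osa_726 (24.7-fold, 17.6 to 35.9) and N_osa_42 (15.8-fold, 13.5 to 18.7) were higher in MS. Among 55 sequences above the minimum, 16 were at least 2-fold higher and 14 at least 2-fold lower. The 24 with a miRNA name leaned lower (5 higher, 8 lower), and the 31 with only a number leaned higher (11 higher, 6 lower).

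Of the 17 listed families above the minimum, 7 were at least 2-fold lower in MS and 4 were higher. miR171, a GRAS regulator, was at 0.443 times (0.404 to 0.486) the US level, and miR394 at 0.873 times. miR169, an NF-Y regulator, was at 0.372 times (0.331 to 0.418) by the table's sum, which rests on miR169r-5p (47.5 against 7.6 RPM), but at 1.41-fold (1.2 to 1.66) as miR169a and miR169b in the tag files. In the NAC, MYB and TCP list miR164 was lower and miR159 higher (3.62-fold, 3.57 to 3.66). In the SPL list miR535 was lower, and miR156 was lower by the table's sum (0.348 times) but at 1.43-fold (1.4 to 1.46) as canonical miR156a-5p in the tag files. In the auxin list miR393 was lower while miR167 was at 0.927 times. miR396 was lower and miR166, which targets HD-ZIP III factors, was at 1.22-fold by the table's sum and at 1.258-fold as canonical miR166a-3p in the tag files. miR827, miR168 and miR1432 were the other families higher in MS, while miR162 (0.872 times), miR1425 (1.6-fold) and miR1850 (1.2-fold) stayed within the limit. miR172 and miR319 were under the minimum in both libraries.

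Late senescence was set against the un-senesced leaf last. miR827 was 17.3-fold higher in LS (15.2 to 19.7), at 309.3 RPM, and miR159f was 7.38-fold higher (7.11 to 7.67), at 1625.7 RPM. miR1432-5p was 5.66-fold higher (5.37 to 5.96), miR159b 2.76-fold (2.72 to 2.81), miR168a-5p 2.42-fold (2.35 to 2.5), miR1425-5p 2.37-fold (2.33 to 2.42) and miR1850.1 2.02-fold (1.865 to 2.182). N_osa_743 (chromosome 10, 11081091 to 11081110) had 0.832 RPM in US and 75.2 RPM in LS (90.5-fold, 51.5 to 175.7), and N_osa_42 was 16.2-fold (13.75 to 19.19) and N_osa_586 411.9-fold (113.6 to 3408) higher. miR164a stood at 0.1745 times its US level (0.1406 to 0.215) and miR396c-5p at 0.203 times (0.187 to 0.22), at 59.2 against 291.6 RPM. miR535-3p stood at 0.233 times (0.202 to 0.267), miR393a at 0.378 times (0.36 to 0.397) and miR167a-5p at 0.386 times (0.34 to 0.437) the US level. Among 60 sequences above the minimum, 22 were at least 2-fold higher and 14 at least 2-fold lower. The 25 with a miRNA name leaned lower (7 higher, 10 lower), and the 35 with only a number leaned higher (15 higher, 4 lower).

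By family, 6 of 18 were higher in LS and 7 lower. The 3 monocot families of the authors' table, miR1432, miR1425 and miR1850, were higher, while miR444 from the tag files was at 1.02-fold (1.01 to 1.03). Nearly all of its reads were miR444b.2. The rarer miR444b.1 was 5.56-fold higher (4.21 to 7.44), at 19.9 against 3.58 RPM. The other families higher in LS were miR827, miR159 (3.33-fold, 3.28 to 3.38) and miR168. miR164, miR396, miR169 (0.209 times, 0.174 to 0.251), miR171 (0.296 times, 0.259 to 0.337), miR535, miR393 and miR156 (0.373 times, 0.299 to 0.463) were lower by the table's sums. From the tag files miR169 was at 1.03-fold (0.841 to 1.26) and miR156 at 1.48-fold (1.45 to 1.51), so neither was lower there. The table's miR396 is miR396c-5p alone, and the 3 miR396 sequences of the tag files were together at 0.316 times (0.301 to 0.331). The table's miR535 is miR535-3p alone, and miR535-5p in the tag files was at 0.151 times (0.0901 to 0.24). miR167 as a family was at its US level (1-fold, 0.985 to 1.01), since miR167d-5p held most of its reads. Within the limit were miR166 (1.18-fold), miR172 (1.68-fold), miR394 (0.646 times) and miR162 (0.731 times), and miR319 was under the minimum. The table's miR166 sum covers only miR166g-3p and miR166k-3p. Canonical miR166a-3p in the tag files was at 1.389-fold (1.369 to 1.409). Tags that hold its bases 4 to 19 had 5947.1 RPM in US and 10827.9 RPM in LS. The scaling weighs on this comparison. TMM and median-of-ratios scaling lower every LS over US ratio by a common 0.33 and 0.44 on the log2 scale. Both scalings leave 14 sequences higher in place of 22, and the higher share of calls is 43.8% and 42.4% against 61.1%. Under TMM miR168 is then at 1.92-fold, miR1425 at 1.88-fold and miR1850 at 1.6-fold.

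**Figure D2:**
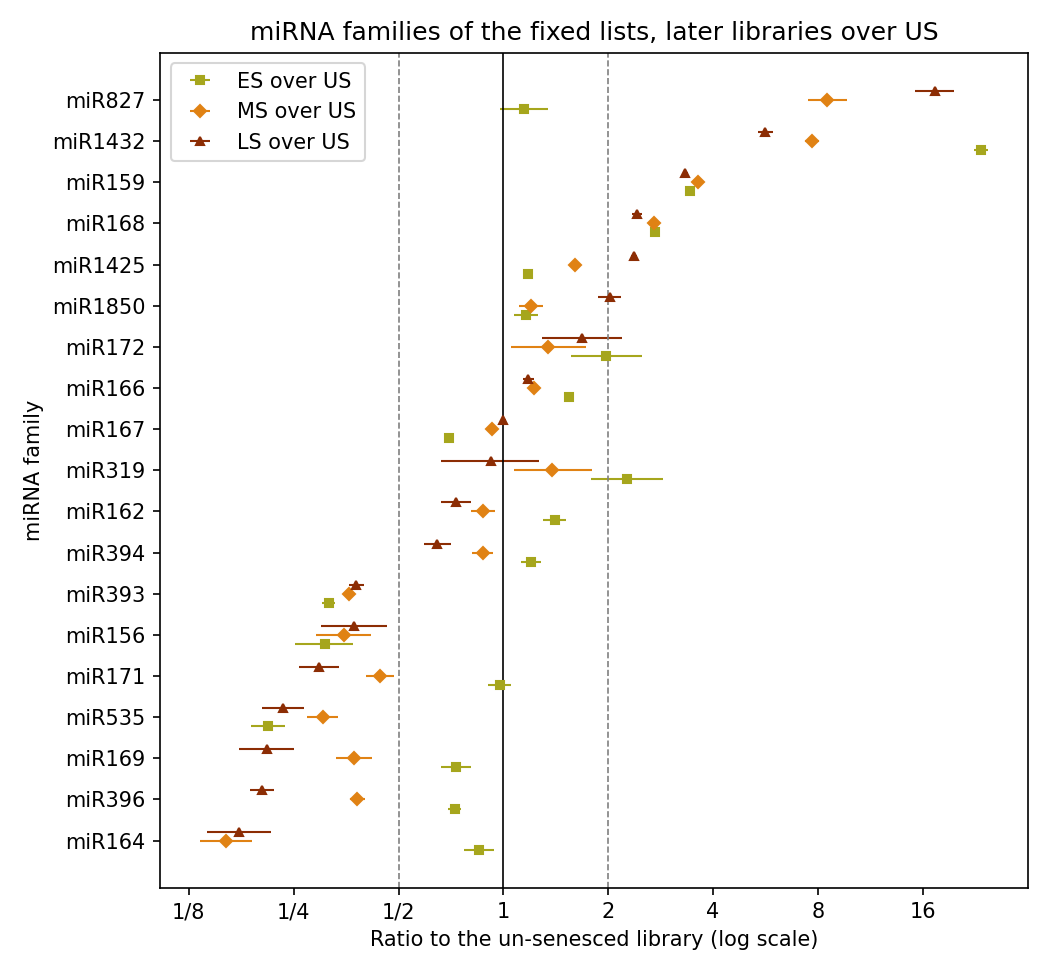
Ratio to the un-senesced library (horizontal axis, log scale) for the 19 listed families above the minimum in any library, with 1 point per later library and 95% counting intervals as bars; dashed lines mark 2-fold either way. miR827 was 17.3-fold and miR159 3.33-fold higher in LS, and miR164 stood at 0.1745 times its US level.

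Successive stages were compared next. From ES to MS, miR827 was 7.45-fold higher (6.72 to 8.28) and miR159f 2.38-fold higher (2.32 to 2.44), while miR1432-5p stood at 0.328 times (0.322 to 0.333), N_osa_194 at 0.386 times (0.345 to 0.431) and N_osa_524 at 0.461 times (0.422 to 0.504) its ES level. Among 55 sequences above the minimum, 6 were higher in MS and 13 lower. From MS to LS, N_osa_743 was 4.52-fold (3.98 to 5.14) and miR827 2.03-fold (1.93 to 2.13) higher, and N_osa_726 stood at 0.469 times its MS level (0.413 to 0.532). Of 55 sequences, 7 were higher in LS and 2 lower. TMM and median-of-ratios scaling each gave 4 higher and 5 lower there, a higher share of 44.4% against 77.8%, and the lowest miR827 ratio over the alternatives was 1.83.

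**Figure D3:**
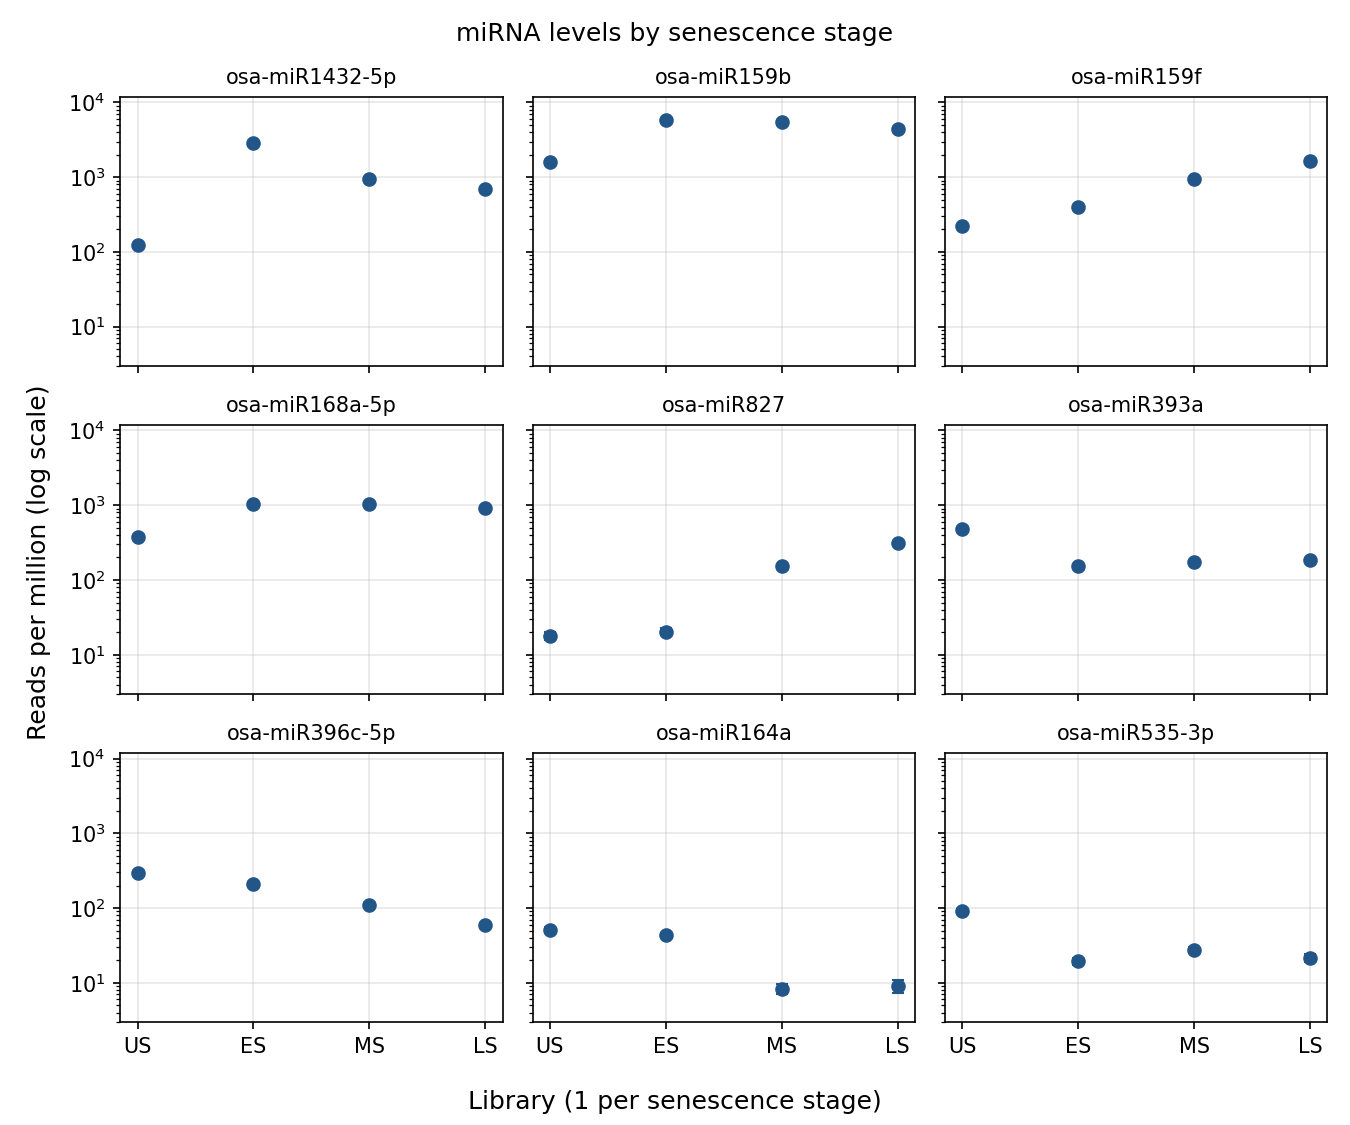
Levels of 9 named miRNAs (RPM, log scale, vertical axis) in the 4 libraries (horizontal axis), with 1 point per library and exact 95% counting intervals as bars, most of them smaller than the points. miR1432-5p was highest in ES at 2903.9 RPM, miR827 and miR159f were highest in LS at 309.3 and 1625.7 RPM, and miR396c-5p was lowest in LS at 59.2 RPM.

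Because the US library stood apart in sequences nearly absent from it or nearly confined to it (3 and 2 of the table), LS was also compared with ES, a comparison chosen after the data were seen. Within these later libraries miR827 was 15.1-fold higher in LS (13.6 to 16.8) and miR1425 2.01-fold higher (1.98 to 2.05). The miR1425 ratio was 1.915 under TMM and 1.84 under median-of-ratios scaling, below the limit. miR1432 stood at 0.241 times (0.235 to 0.246), miR164 at 0.204 times (0.165 to 0.251), miR396 (miR396c-5p alone) at 0.28 times (0.258 to 0.303), miR169 at 0.286 times (0.238 to 0.343), miR171 at 0.303 times (0.266 to 0.344) and miR319 at 0.407 times (0.308 to 0.53) its ES level. Over the 3 miR396 sequences of the tag files, the family was at 0.423 times its ES level (0.403 to 0.443). miR159 (0.971 times), miR168 (0.887 times), miR393 (1.2-fold) and miR535 (1.1-fold, miR535-3p alone) were within 2-fold of ES. The miR159 sum covers 2 members that moved apart, miR159f from 397.7 RPM in ES to 1625.7 in LS and miR159b from 5761.8 to 4354.3 RPM. miR535-5p in the tag files was at 0.631 times its ES level (0.36 to 1.06), from 60 reads in ES and 20 in LS. Among 61 sequences above the minimum, 12 were higher in LS and 20 lower.

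The remaining listed families were read from the tag files, as reads of known mature sequences in RPM of all tag reads. Of the copper and redox list, miR408, which targets plantacyanin-type proteins, was at 193 RPM in US, 150.4 in ES, 70.7 in MS and 68.6 in LS, or 0.356 times the US level in LS (0.33 to 0.383). miR398, which targets copper/zinc superoxide dismutases, was at 221.7, 372.7, 158.8 and 96.7 RPM in the same order, and 0.436 times its US level in LS (0.409 to 0.465). miR397, by its canonical sequences alone, was at 16.5 RPM in US and 15.1 in ES, lower in MS at 7.83 RPM (0.475 times, 0.392 to 0.573), and at 9.04 RPM in LS (0.548 times, 0.438 to 0.683), and miR528, a regulator of ascorbate oxidase, was at 118.3 RPM in US, 142.7 in ES, 76.2 in MS and 109 in LS. miR390, which triggers the TAS3 siRNAs, was at 12 RPM in US, 12.3 in ES, 1.04 in MS and 1.74 in LS. miR820, which targets a DNA methyltransferase, was 2.98-fold higher in ES than in US (2.42 to 3.7), and 1.83-fold and 1.8-fold in MS and LS. miR444, a regulator of MADS-box genes, was at 6300.6, 7833, 9804.3 and 6424.5 RPM. miR395 and miR399 stayed under 1 RPM in every library, as miR530 was under 2 RPM. Each was looked up by 1 exact sequence (miR395b, miR399a and miR530-5p), and other members or shifted forms were not counted. miR160 and miR529 were below the minimum of 10 RPM in the authors' table. The panicle markers miR2118 and miR2275 were looked up by 1 sequence each, written from general knowledge, and these exact sequences had 0 reads in each library, which allows for each up to 0.168 RPM in US, 0.126 in ES, 0.13 in MS and 0.238 in LS.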

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

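The first test of genotype and the test of over-amplification were set before their results were seen; all other tests below were chosen afterwards.

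Signal outside the authors' miRNA table was looked for in the tag files, with no control sample to set it against. Only 3 tags outside the table passed 10000 RPM in a library. TAATTCATGATCTGGC reached 61658 RPM in ES and 405.2 RPM in LS. AGCGGAGTAGAGCAGTT reached 32517 RPM in LS and 316.8 RPM in ES. CAGTTACTAATTCATGATCTGGC reached 24152 RPM in US and at least 14355.3 RPM in each library. Families that the table does not list by name also passed 10 RPM by their known mature sequences, with highest values of 9804.3 RPM for miR444 (MS), 372.7 RPM for miR398 (ES), 193 RPM for miR408 (US), 142.7 RPM for miR528 (ES), 18.68 RPM for miR820 (ES), 16.49 RPM for miR397 (US) and 12.27 RPM for miR390 (ES). The table holds shifted or longer forms of miR397 and miR820 under numbers, N_osa_114 and N_osa_574 for miR397 and N_osa_90 for miR820.

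N_osa_586, N_osa_524 and N_osa_227 were at least 50-fold lower in US than in each later library, and N_osa_492 and N_osa_702 at least 50-fold higher, while no sequence met these limits for ES, MS or LS. Lower depth of US is argued against by the library totals. US held 17886772 reads, fewer than ES and MS but more than LS with 12609518, where no sequence met these limits. A median of 525.1 reads was expected in US at the lowest later level and a median of 2 was seen. The 50-fold limit that picked these sequences fixed such a gap in advance, so it adds nothing. If US came from plants of another genotype, tags private to it should have partners that differ by 1 base and are missing from US. The test set beforehand, which required 0 reads on the absent side, found 0 such pairs in US and so gave it no support; it cannot exclude it either, because ES, MS and LS had 0 missing tags and could give no pairs to compare with, 23.54% of single-base neighbours of abundant US tags had a read in US and 7 of the 12 partners found later had at least 1. With 20-fold limits in place of 0 reads, a version chosen after that result, US had 12 pairs in 7 groups of overlapping tags. Examples are T13C, G8A and C9G, the US base first, positions from the 5′ end. The highest value in 1000 draws of 97 other abundant tags was 2. All 3281 tags drawn from held 5 such pairs together, so no draw could have reached 12. Overlapping tags of the same site were counted as separate pairs, so the number of pairs overstates the separate differences. Another genotype, a seed mixture or a mislabelled sample may explain the pairs as a hypothesis. Opposite regulation of near-identical copies was not tested and, like the stage itself, stays open.

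Reads of 16 nt held about 3 times as large a share in US and ES as in MS and LS. A few tags held most of this difference, but they are argued against as the whole cause. The same 16-nt tag was the most abundant of that length in US, ES and MS. It held 5.532% of all US reads, 6.166% in ES and 0.3229% in MS, and had 405.2 RPM in LS. The 10 most abundant 16-nt tags of each library held 64.31% of the 16-nt reads of US and 34.49% of those of MS. Without those tags the 16-nt shares were 5.917% in US, 6.743% in ES, 3.491% in MS and 2.201% in LS. The lower of the US and ES shares was then still 1.695 times the higher of the MS and LS shares. A lower size cut in gel excision of US and ES cannot be told apart from other causes. The 17-nt shares without their top tags were 5.039% in US, 5.716% in ES, 4.792% in MS and 3.572% in LS. The mean of US and ES was 1.286 times the mean of MS and LS, between the limits set for either answer. The 16-nt ratio of 1.695 compared single libraries and not means, so the ratios are on unlike measures. By single libraries, the 17-nt shares of US and MS lay close together, so the answer depends on the measure. Over all 17-nt reads the share was highest in LS (6.763% in US, 7.454% in ES, 6.797% in MS and 7.905% in LS), where the 10 top tags held 56.85% of them. RNA breakdown and the stage itself were not tested.

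miR1432-5p was 23.5-fold higher in ES than in US. Over-amplification of a single tag as the whole cause in ES is argued against, since the 10 tags of the opposite strand were together 11.19-fold higher in ES (8.682 to 14.65). They were 1.897-fold in MS (1.409 to 2.579) and 1.108-fold in LS (0.75 to 1.63), so the check does not extend to those libraries. Opposite strands did not always follow their miRNA, which limits the check. That of miR159b was 13.48-fold higher in ES, where miR159b was 3.66-fold higher. Normalization by a library total is argued against as well, since the lowest ratio over TMM, median-of-ratios and tag-file totals was 18.98. Tag-file totals are themselves a library total. Each scaling changes all ES over US ratios by a common factor, with a largest log2 shift of -0.31. The check is therefore not particular to this miRNA. The difference in stage stays open as a hypothesis, as does a difference in genotype between these libraries, and neither was tested for this miRNA.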

How the results depend on the processing

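TMM was the planned scaling and was kept as an alternative when the deposited values took its place. The tag-file families, the LS against ES comparison and every alternative for the ratio of a single miRNA or family were chosen after seeing the data. The other alternatives for counts and length shares were planned. No named miRNA reversed its direction under any scaling or the recount, nor any called family under any scaling, and 41 of 45 named ratios stayed at least 2-fold under all of them. From known mature sequences in the tag files, 33 of 38 called family ratios kept their direction and 5 reversed. miR156 was at 1.742-fold in ES, 1.431-fold in MS and 1.482-fold in LS, and miR169 at 1.413-fold in MS and 1.031-fold in LS, where the sequences summed differ from those of the table. The named ratios that fell below 2-fold were those of miR168a-5p (lowest ratio 1.79), miR1425-5p (1.75) and miR1850.1 (1.49) in LS against US and miR827 (1.83) in LS against MS. Of the alternative counts, 49 of sequences and 37 of families stayed within 1.5 times the reported count, while 35 and 5 did not; the filter settings change the number of sequences compared, and for the others the cause was not tested. TMM and median-of-ratios scaling shift ratios over US by -0.26 and -0.31 (ES), -0.19 and -0.30 (MS) and -0.33 and -0.44 (LS) on the log2 scale. No paired analysis was possible because each stage had 1 library.

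With no filter, the sequences higher and lower numbered 107 and 47 for ES against US, 120 and 62 for MS against US, 141 and 62 for LS against US, 56 and 50 for MS against ES, 44 and 23 for LS against MS, and 76 and 61 for LS against ES. With a minimum of 100 RPM they numbered 5 and 1, 6 and 3, 8 and 2, 2 and 1, 1 and 0, and 4 and 3 in the same order. TMM and median-of-ratios scaling each gave 14 higher for LS against US, and 4 higher and 5 lower for LS against MS. For LS against MS, tag-file totals and the recount from the tag files each gave 1 lower, and the nearer bound of the counting interval gave 4 higher and 1 lower. That bound gave 3 higher for MS against ES.

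Families lower than US with a minimum of 100 RPM numbered 1 in ES, 2 in MS and 2 in LS, and 3 were higher in LS under TMM and under median-of-ratios scaling.

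Each alternative moved every length share beyond its counting interval. The 21-nt share in US, ES, MS and LS was 10.22, 11.16, 11.46 and 12.49% of distinct tags, 17.37, 22.09, 22.13 and 21.73% of reads of 18 to 26 nt, and 13.99, 18.31, 21.08 and 20.34% among tags seen at least 2 times. The 24-nt share was 37.92, 32.17, 28.55 and 27.33%, then 28.38, 24.09, 21.98 and 19.58%, then 16.25, 13.87, 14.27 and 11.72% in the same orders. The 24-nt share was highest in US and lowest in LS under each setting, and the 21-nt share was lowest in US. Depth limits the lowest sequences: 3 reads equal 0.168 (US), 0.126 (ES), 0.13 (MS) and 0.238 RPM (LS) of the tag reads.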

Other observations

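The comparisons of opposite strands and of private tags below were chosen after the data were seen.

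The opposite strands of other miRNA hairpins were also measured in the tag files. That of miR159b was 13.5-fold higher in ES than in US (9.95 to 18.7) but 2.55-fold in LS (1.74 to 3.77), where miR159b itself was 3.66-fold and 2.76-fold higher. The opposite strand of miR159f was 7.84-fold higher in LS (5.867 to 10.65), beside 7.38-fold for miR159f. For miR168a-5p the opposite strand was 2.77-fold, 4.32-fold and 3.18-fold higher in ES, MS and LS. That of miR1425-5p was 1.48-fold higher in LS (1.4 to 1.57), beside 2.37-fold for the miRNA. The opposite strand of miR1432-5p was 1.11-fold in LS (0.75 to 1.63), where the miRNA was 5.66-fold higher. The opposite strand of miR827 had 3, 1, 3 and 2 reads in US, ES, MS and LS, too few to compare with the miRNA (0.946-fold in LS, 0.079 to 8.26). That of miR396c-5p stood at 0.334 times its US level in LS (0.134 to 0.735), beside 0.203 times for the miRNA. The opposite strand of miR164a had 4, 19, 13 and 15 reads in US, ES, MS and LS, and was 5.32-fold higher in LS than in US (1.7 to 22), where miR164a itself stood at 0.1745 times its US level.

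Reads around miR397 were almost all shifted from the canonical sequence. Tags that hold its bases 4 to 19 made up 11430.2, 9416.6, 6012.3 and 7518.1 RPM in US, ES, MS and LS, and the exact miR397a sequence was 0.141, 0.157, 0.128 and 0.117% of them. The authors' numbered sequences held 70.26, 50.72, 48.04 and 53.53% of the table's reads in the same order. Of those, 95.75, 90.51, 90.25 and 91.43% lay in the 5 numbered sequences that overlap known miRNAs.

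The MS library held 158 tags of 20 to 24 nt with at least 5 RPM and 0 reads in the other libraries, against 76 in US, 0 in ES and 5 in LS. In US 64 of the 76 had 24 nt, while those of MS were spread over lengths, with 39, 46, 33, 22 and 18 tags of 20, 21, 22, 23 and 24 nt. Of the 158 tags, 23 matched a tag abundant in the other libraries from base 4 on. Together the 158 tags held 35576 reads, or 0.155% of the MS library.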
